A study of Mus musculus with 2 samples.

How the data were processed

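Binding of Zic3, a zinc finger transcription factor of the Gli-related Zic family, was measured in E14 mouse embryonic stem (ES) cells by chromatin immunoprecipitation followed by hybridisation to promoter tiling arrays (ChIP-on-chip). Per the labels' protocols, the immunoprecipitated DNA carried the Cy5 (red) dye and whole cell extract, the input, carried the Cy3 (green) dye, and both had been amplified by ligation-mediated PCR. A positive log ratio of red over green therefore stood for more ChIP DNA than input DNA.

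There were 2 arrays in 1 group, numbered replicate 1 and replicate 2 in the order of their records. They carried different probes of a promoter set: array 1 held chromosomes 1 to 8 and part of chromosome 9, and array 2 held the rest of chromosome 9, chromosomes 10 to 19 and X, Y and M. No tiled probe was on both, so each promoter was measured in 1 hybridisation, and no test between replicates could be made. The series' design text speaks of biological replicates, and further hybridisations were not analysed here.

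Per the file headers, the spots had been quantified with Feature Extraction 9.5.3.1. The processed intensity of each channel was, per the file headers, background-subtracted, spatially detrended and linearly dye-normalized, and the mean and background intensity of each spot were deposited beside it. The log10 ratio and its error were deposited in the same files as the software computed them from the processed intensities. The p-value of the software's error model was deposited per spot and was used only in an alternative calling rule. The value table of the series held the same log10 ratios as the scanner files (largest difference 0), uncentred, with medians of 0.0116 and 0.0126 on array 1 and array 2. The genome build behind the probe coordinates was not given in the sources used here, so positions are printed as the files give them.

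Control spots were left out, as were 114 and 361 tiled spots marked as non-uniform or population outliers, which left 237081 and 236824 probes at a median spacing of 178 and 177 bp. Both channels were well above background at 99.7% and 99.5% of these probes, and 4 probes on each array were saturated. The median processed intensity was 767 for input and 783 for ChIP on array 1, and 764 and 785 on array 2. Each log2 ratio was centred on its array's median, and its spread was taken as the median minus the 16th percentile, 0.69 on both arrays, so that true enrichment did not widen it. A probe was called at a one-sided normal tail of 0.001, which was a log2 ratio of 2.14 on array 1 and 2.12 on array 2, where an adjacent probe within 1000 bp passed a tail of 0.005. Called probes and their supporting neighbours at most 1000 bp apart were merged into bound regions. The same rule with the sign of the ratio turned gave the number of calls that noise would produce if it were symmetric at every probe. It counts false calls only as far as that holds. Genes were named from the annotation of the probes in a region. Of 17708 annotated transcripts, 16671 were matched by accession to current mouse symbols (RefSeq names of GRCm38.p6, used for names alone), 395 by symbol and 378 by synonym, and 264 kept the name in the files. There were 17042 measured genes.

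The gene score was the highest mean log2 ratio of 3 adjacent probes within 1000 bp of each other, available for 16813 genes. There were 18 gene lists, and the median score of each was placed among 10000 random lists of the same size matched on probes per gene (5 bins) and on mean input signal (5 bins). A list was said to stand apart when its median fell outside the central 95% of its random lists. This describes these hybridisations and is no test across replicates. Words for the Zic core (CAGCAGG) and a Gli-type site (GGGTGGTC), on either strand, were counted in the probe sequences of bound regions, in unbound windows of as many probes and like GC content, and beside letter permutations of each word. Word counts had been planned for a genome of the files' own build. None was used here, so the probe sequences, which cover only part of a region, took its place. Intervals of shares are 95% Wilson intervals and cover counting error only. For shares of called probes they take the probes as independent, although each call needs a passing neighbour, so those intervals are too narrow.

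The named genes were, by a rule set before the data were examined, the 20 highest gene scores among bound genes (genes of a shared region counted once), up to 8 bound members of the pluripotency, left-right and Nodal, and Hedgehog and Zic lists, the 3 highest bound members of each other list, and Nanog, Pou5f1, Sox2 and Zic3. Nanog had no probe under its symbol and was not analysed here. The lists, the calling rule and most alternatives were also fixed then. Alternatives were normexp background correction (offset 50), loess, uncentred ratios, the value table, other spreads, tails and neighbour rules, filters on dim or outlying spots, removal of the trend on probe GC content, the software's error model and each array alone. A joint correction for GC content and input signal was added after the data had been seen.

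The calling rule was tested on simulated data: correlated noise on the real positions of 473905 probes with 200 added regions. It found 22.4% of regions with a peak log2 ratio of 2, 68.7% at 3 and 87.9% at 4, with 58 regions elsewhere and 66 with the sign turned. The simulated noise was normal with a neighbour correlation of 0.34, that of the ratios after the joint correction. The uncorrected ratios, on which the main rule ran, had 0.61 on array 1 and 0.60 on array 2. The simulated shares and counts therefore need not hold for the main rule on these data. In a simulated list of 40 genes among 16813, a shift of 0.5 gave a median above all random lists. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, R 4.3.3 and limma 3.58.1 (normexp and loess).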

Results

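Zic3 occupancy was profiled over the promoters of E14 mouse ES cells, a line that grows as undifferentiated pluripotent cells, as the ratio of Zic3 ChIP DNA to input DNA. The 2 arrays of the single group held different promoters, so every value below comes from 1 hybridisation. The error given with a single probe is that of the scanner software's error model (its median was 0.22 on the log2 scale on both arrays), and the SD given with a gene score is the spread of its 3 probes. The software's error was below the lower-side spread of the ratios, 0.69 on both arrays, and is no spread between hybridisations. Between the hybridisations, the only probes in common were control probes. The largest class, 3104 control probes with names starting LACC, had log2 ratios that correlated between the arrays at a Pearson r of 0.94. A smaller class, 100 DCP control probes, had 0.91. These are correlations across probes and not across replicates. For the LACC probes the difference between the arrays had an SD of 0.21. Scaled to a single array, that was an error of 0.15, and 0.06 by a robust estimate. It is not the spread of the LACC ratios themselves.

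The first question was which promoters carried Zic3. The highest gene scores belonged to Mbtps2, a membrane protease that processes transcription factors, at 3.47 ± 1.51 (SD of 3 probes), Mycn, a Myc family transcription factor, at 3.27 ± 0.31, and Ror1, a receptor tyrosine kinase-like protein of Wnt5a signalling, at 2.99 ± 0.35. At Mycn, 5 probes on chromosome 12 from 13005831 to 13006368 formed the region, and the peak probe, at -1941 bp from the annotated start, had a log2 ratio of 3.59 ± 0.40 for ChIP over input. The Ror1 region covered 7 probes inside the gene (chromosome 4, 99473403 to 99474471), with its peak of 3.35 ± 0.38 at 1380 bp. The Mbtps2 region (chromosome X, 152375740 to 152376380) held the highest peak of all bound regions, 5.16 ± 0.54 at -3140 bp, and its probes differed more among themselves than those of Mycn or Ror1.

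Genes of several kinds made up the rest of the 20 highest. Agtrap scored 2.89, Cd38, an NAD-hydrolysing ectoenzyme, 2.87, and Gja1, a connexin of gap junctions, 2.84. The co-repressor Trim28 shared a region with Zbtb45 on chromosome 7 (11600553 to 11601413) at a score of 2.81. Hs6st2, a heparan sulfate sulfotransferase, also scored 2.81, and Tdgf1 scored 2.73 in a region shared with Lrrc2. Fgfbp1 followed at 2.71, the histone acetyltransferase Kat7 at 2.68, the metalloproteinase inhibitor Timp4 at 2.66, and Ppp1r10 at 2.66. Spred1, an inhibitor of Ras signalling, scored 2.64, Lrrn2 2.61, the hypothalamic hormone precursor Trh 2.59, and Casq2, a calcium-binding protein of muscle, 2.56. Uhrf2 at 2.55, Il17d at 2.53 and Trp53bp1, a DNA damage response protein, at 2.52 closed the list. Its order depended on the processing. After the joint correction for GC content and input signal, Mycn scored 3.54, Cd38 3.25, Mbtps2 3.20 and Ror1 3.17.

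In all, 363 probes were called, 194 on array 1 and 169 on array 2, against 56 with the sign turned. They formed 227 bound regions against 48, and the regions named 229 genes against 50. The turned count was thus 21.1% of the regions, but it fell with height. Of the regions with a probe above 2.5 there were 111 against 6, and above 3 there were 39 against 0. Called and turned probes lay in different classes of input signal. The lowest of 10 classes held 139 called and 0 turned probes, and the highest held 3 and 15. The turned count is therefore no rate of false calls for probes with low input. With stricter tails the counts were 64 regions and 68 genes, and 0 regions with the sign turned. Regions had a median of 2 probes and a median width of 235 bp, and their peak log2 ratios ranged from 2.13 to 5.16 with a median of 2.48. The genes in the list depended on the normalization. Of the 229 genes, 124 were also bound with median and spread taken in 20 bins of input signal, 161 with loess and 130 with normexp. Regions with the sign turned were also more frequent under these settings, 128 beside 273 with input bins, 144 beside 309 with loess and 158 beside 225 with normexp.

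Genes of the ES cell pluripotency network stood above all other lists. Of 42 measured members, 9 had a bound region, against a mean of 0.63 in matched random lists (central 95%, 0 to 3), and the list's median score of 1.25 exceeded every 1 of the 10000 random lists, whose median was 0.74. The bound members were Tdgf1 (Cripto, a Nodal co-receptor), Trp53, Jarid2, Sox2, Pou5f1, Sall2, Eras, Rif1 and Sall4, the last of which fell outside the rule of 8 named members. None of the 42 was called with the sign turned.

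**Figure D1:**
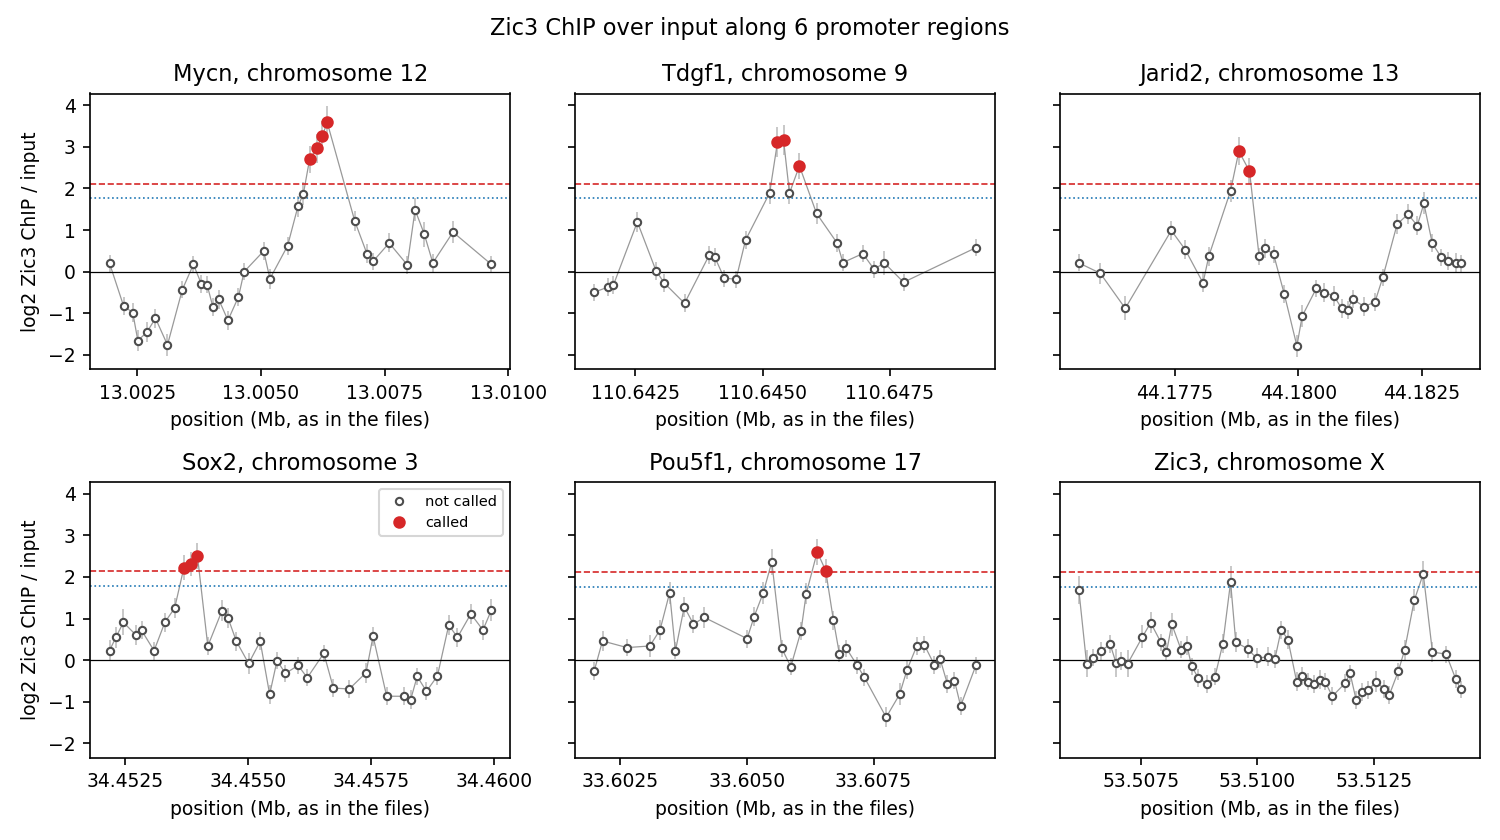
Log2 ratio of Zic3 ChIP over input (y axis) against position in Mb (x axis) for each probe at 6 promoters, with error bars from the scanner software's error model, the probe threshold as a dashed line and the neighbour threshold as a dotted line. Called probes (filled) rise above 2.1 at Mycn, Tdgf1, Jarid2, Sox2 and Pou5f1, and Zic3 has no called probe.

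At Sox2, which encodes an HMG-box factor of the core ES cell circuit, 3 adjacent probes on chromosome 3 (34453662 to 34453995) had high ratios together, with a score of 2.35 ± 0.14 and a 5.67-fold peak at -3469 bp. At Pou5f1, which encodes Oct4, the bound region on chromosome 17 (33606367 to 33606578) peaked at 2.60 ± 0.32 at -937 bp, a 6.08-fold excess. Jarid2, a subunit of Polycomb repressive complexes, peaked at 2.90 ± 0.34 at -2190 bp. Trp53 peaked at 3.18 ± 0.36 at 2060 bp, inside the gene. Sall2 (2.82 ± 0.34) and Eras (2.39 ± 0.34) also peaked inside the gene, at 2305 and 2309 bp, and Rif1 peaked at 2.27 ± 0.30 at -657 bp. Members with low scores, picked after their values were seen, were Klf4 at 0.37, Esrrb at 0.45 and Dnmt3l at 0.14. With the stricter tails, Sox2, Eras, Rif1 and Sall4 were no longer called. Under the main rule, 3 of the 23 members on array 1 and 6 of the 19 on array 2 were bound.

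Of the listed left-right asymmetry and Nodal pathway genes, the processes disturbed by Zic3 mutation in mammals, 0 of 29 had a region, and the list's median of 0.82 lay at a percentile of 92.4 among its random lists. Tdgf1, the Nodal co-receptor gene with a bound region, was counted in the pluripotency list and not in this one. The 0 therefore covers the listed genes only. Named here after its value was seen, Nodal had a peak probe of 2.73 ± 0.33 at -2142 bp that passed the probe threshold without a passing neighbour, and Lefty1 had 2.36 ± 0.30 at -1069 bp, likewise alone. In the Hedgehog and Zic list, Zic2 and Zic5, which share a divergent promoter, had a region on chromosome 14 (116872736 to 116872943) that peaked at 2.21 ± 0.30 and was lost with stricter tails. They were the 2 bound members of 27, and the list's median stood at a percentile of 28.5, and at 98.3 on array 2 alone. Zic3 itself, with 51 probes, had no bound region. Its score was 1.25, rank 2461 of all genes, and its highest probe had 2.08 ± 0.30 at 2205 bp.

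Ribosomal protein genes, which are transcribed at high levels in growing cells, and olfactory receptor genes, which are expressed mainly in the olfactory epithelium, were the other lists to stand apart. The ribosomal median of 0.77 lay at a percentile of 99.9, above the random median of 0.61, while 0 of 83 members had a region and 3 were called with the sign turned. On array 1 alone the ribosomal list lay at a percentile of 85.6. The 842 olfactory receptor genes had a median of 0.94, below all random lists (central 95%, 1.01 to 1.05), and 6 of them had a region against a mean of 12.8 in random lists. The highest 3 were Olfr623 (1.97), Olfr33 (1.90) and Olfr1427 (1.82), and none of these was bound with median and spread taken in 20 bins of input signal, while Olfr623 stayed bound with loess.

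Among the remaining lists no median stood apart. Oncogenes and tumour suppressors had 2 of 54 bound, Mycn and Nras (score 2.02, also lost with the 20 bins), at a percentile of 87.5, and at 99.4 on array 1 alone. The bound gene Trp53 was counted in the pluripotency list and not in this one. The Fgf and Bmp list had 1 of 35 bound, the Ets factor Etv5 (1.70), at 79.8. The Wnt list had 1 of 44, Porcn (2.18), which acylates Wnt proteins, at 75.2. Chromatin regulators had 1 of 34, the Polycomb gene Phc1 (2.08), at 64.0. Of the bound genes named above, Jarid2 was counted in the pluripotency list, and Kat7 and Trim28 were not in the chromatin list. Mesendoderm genes had 1 of 45, the Wnt antagonist Dkk1 (2.26), at 33.7. Fibroblast markers had 1 of 19, the intermediate filament gene Vim (2.33), at 20.9, and normexp ended that call. Hox genes had 1 of 33, Hoxb13 (2.03), at 15.5. No region was found in neurectoderm (43 genes, percentile 84.3), cell cycle (59 genes, 83.6), liver and plasma protein (27 genes, 43.0, and 0.05 with normexp), keratin (78 genes, 30.0, and 1.23 with normexp), vomeronasal receptor (107 genes, 21.9, and 1.62 on array 1 alone) or trophectoderm genes (18 genes, 14.1, and 1.22 with the GC trend removed). The stricter tails also ended the calls at Etv5, Porcn, Phc1, Dkk1, Vim, Hoxb13, Nras, Olfr33 and Olfr1427.

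**Figure D2:**
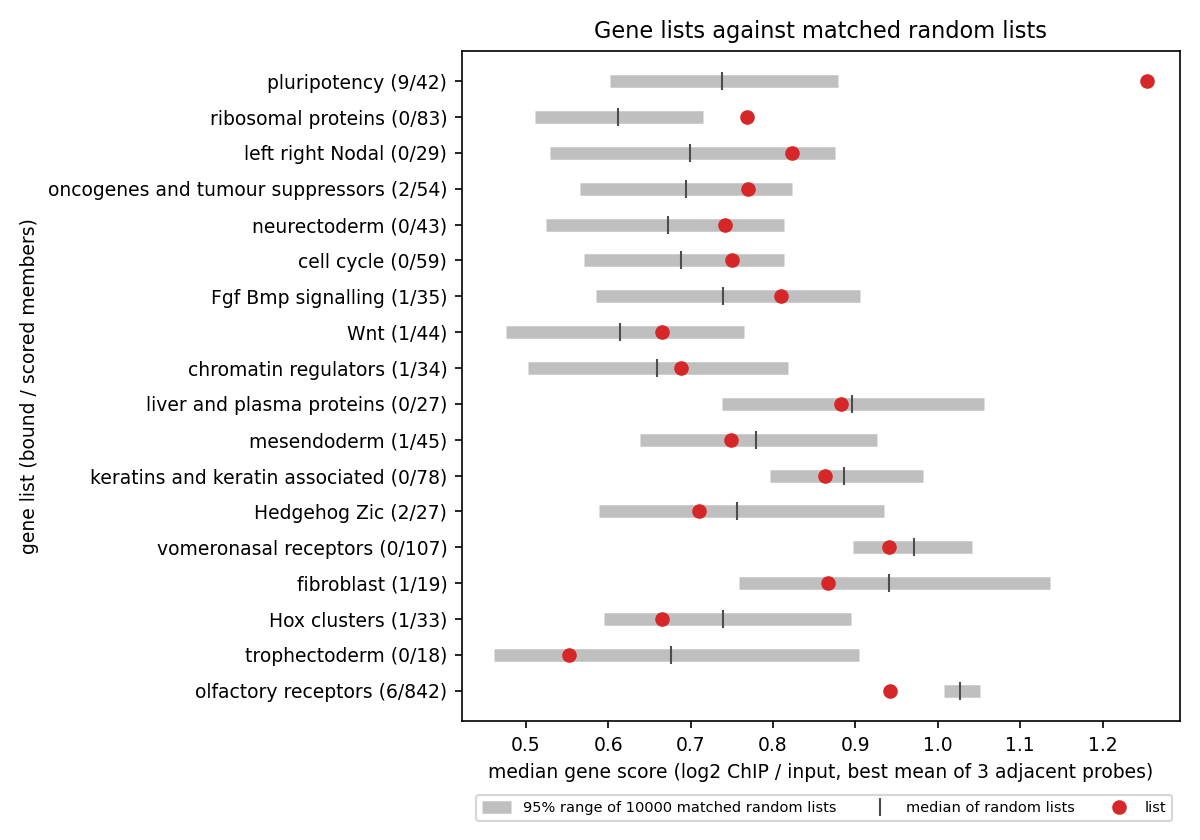
Median gene score of each gene list (points, x axis, log2 ChIP over input) with the median (ticks) and central 95% (bars) of 10000 matched random lists, and bound over scored members in brackets. The pluripotency list lies at 1.25, and its random lists reach 0.88 at the upper end of the central 95%.

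Under the main rule, called Zic3 probes were less frequent near the transcription start than tiled probes. Of the 360 called probes with a distance, 25 were within 500 bp of the start, 6.94% (4.75 to 10.1), whereas 16.7% of all tiled probes and 51.8% of those called with the sign turned were. Counted by region, 14 of 224 peaks (6.25%) lay within 500 bp. The share was highest between -2000 and -1000 bp, with 20.6% (16.7 to 25.0) of called probes against 10.7% of tiled ones. Of 224 regions with a distance, 146 peaked upstream of the start and 116 of these (51.8% of the 224) more than 1000 bp upstream, as at Mycn, Tdgf1, Jarid2 and Sox2. Much of the tiling lay there too. The tiled share was 12.1% below -4000 bp, 8.26% from there to -3000 bp, 9.24% to -2000 bp and 10.7% to -1000 bp. Among the 20 highest, Trp53bp1 (-40 bp) and Timp4 (-462 bp) peaked near the start, and Ror1 (1380 bp), Cd38 (577 bp) and Ppp1r10 (1075 bp) peaked inside the gene. The share within 500 bp rose to 10.7% with the GC trend removed and 12.2% with normexp. Once the trends with probe GC content and input signal were both removed, an alternative added after the data had been seen, it was 14.5% (11.9 to 17.5), an interval that held the tiled share. The share between -2000 and -1000 bp was then 15.5% (12.8 to 18.6).

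**Figure D3:**
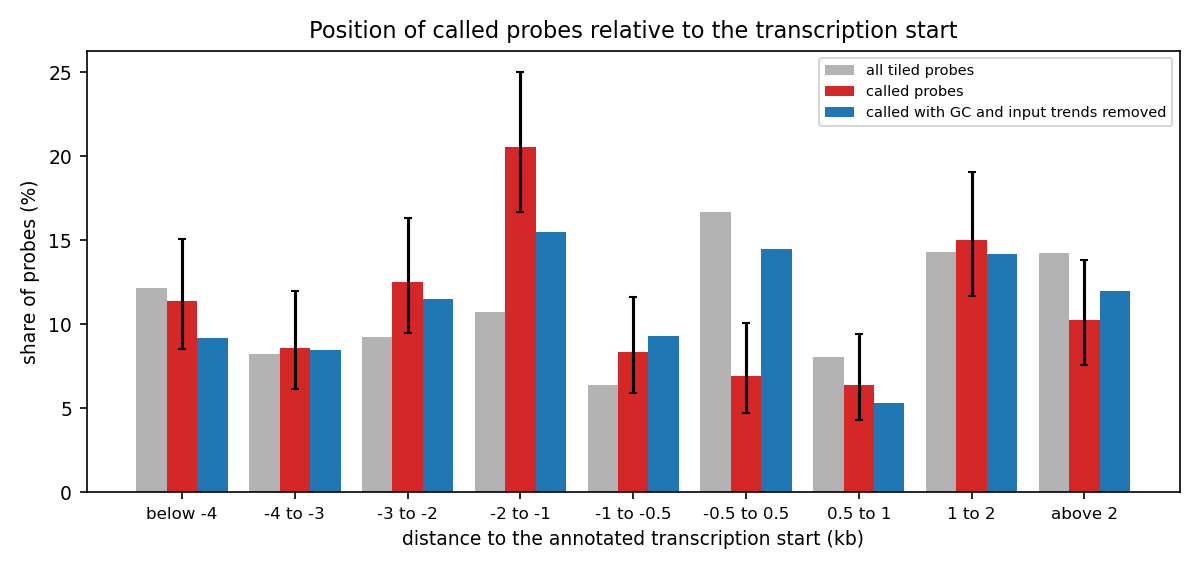
Share of probes (y axis, %) per class of distance to the annotated transcription start (x axis, kb) for all tiled probes, called probes (with 95% Wilson intervals) and probes called with the GC and input trends removed. Called probes hold 6.94% within 0.5 kb of the start, and 14.5% with the trends removed, against 16.7% of tiled probes.

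The Zic core word CAGCAGG was in the probe sequences of 3 of 227 bound regions, those of Fas, Ctso and Nphs2 (named after they were seen), which was 1.32% (0.45 to 3.81) against 1.06% of matched unbound windows. That excess was matched or passed by 11 of 59 letter permutations of the word. Fas, Ctso and Nphs2 were not among the 122 genes bound under the main rule and all of its alternative normalizations compared below. The Gli-type word GGGTGGTC was in 0 of 227 regions (upper limit 1.66%) against 0.04% of windows. So rare a word could not be compared in this number of regions, and the 0 speaks neither for nor against a preference. With the spread in 20 bins of input signal, the core word was in 4.03% of regions against 1.83% of windows, an excess above every permutation, and with stricter tails it was in 0 of 64.

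The ratio followed the base composition of the probes. Across the 473905 probes, GC content and log2 ratio had a Pearson r of -0.51 on array 1 and -0.50 on array 2 (across probes, which are not independent replicates). The median log2 ratio rose from 0.07 for probes of 20 to 25% GC to 0.35 for probes of 30 to 35% GC, and fell to -0.99 for probes of 75 to 80% GC. Among 10 equal classes of input signal it went from 0.79 in the lowest to -0.61 in the highest. Input signal is the denominator of the ratio, so noise in the input alone would lower the ratio as input rises. That part of the trend was not separated. Bound regions had a median GC content of 37.5%. Removing the GC trend kept all of the 229 bound genes, Pou5f1 and Sox2 among them, and raised the count to 408 against 216 with the sign turned.

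**Figure D4:**
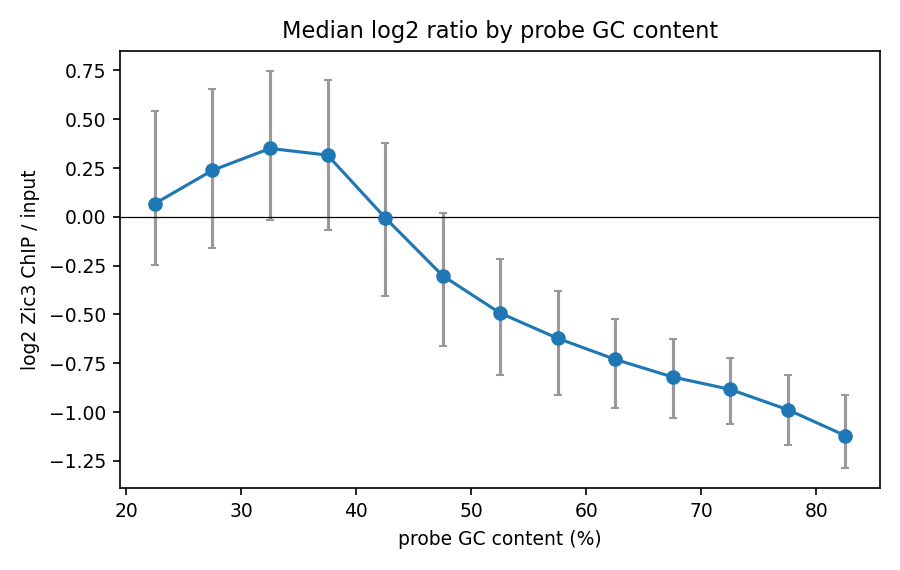
Median log2 ratio of Zic3 ChIP over input (y axis) by class of probe GC content in % (x axis), with bars for the interquartile range of the probes in each class, over both arrays. The median rises from 0.07 at 20 to 25% GC to 0.35 at 30 to 35% GC and falls to -0.99 at 75 to 80% GC.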

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

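Of the 3104 LACC control probes on both arrays, whose correlation is given above, 5 passed the probe threshold on both arrays and 0 did so with the sign turned. Ratios of these probes repeated between the arrays (Pearson r 0.94 across probes), and what raised these 5 was not tested.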

How the results depend on the processing

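The joint correction for GC content and input signal was chosen after the data had been seen, as were the GC correction for the core word and the GC correction combined with matching on GC. With 1 hybridisation per probe, no spread between replicates bounds any count. Both channels were well above background at nearly all probes, but calls gathered at low input. Of the 363 called probes, 139 lay in the lowest of 10 classes of input signal, which is also the denominator of the ratio.

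The 363 called probes became 627 with loess, 586 with 20 bins of input signal, 91 with stricter tails, 1380 with no neighbour needed, 696 with the GC trend removed, 34720 under the error model and 603 with GC and input bins. Each array alone gave 169 to 194. The 227 regions became 64 with stricter tails, 1224 with no neighbour needed, 408 with the GC trend removed and 13837 under the error model, and 112 to 115 on each array alone. The 229 genes became 68, 1178, 408 and 9414 under those settings, and 112 to 117 on each array alone. The error model called more probes with the sign turned (49204). Turned calls count noise only where it is symmetric, so these calls cannot be read as enrichment, nor as its absence. All other counts stayed within 1.5 times.

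The share of called probes within 500 bp of the start (6.94%) was 12.2% with normexp, 11.4% with loess, 13.4% with 20 bins of input signal, 10.7% with the GC trend removed and 14.5% with GC and input bins, against 16.7% of tiled probes, and 5.24% to 8.88% on each array alone. The interval included the tiled share with GC and input bins (11.9 to 17.5) and with stricter tails (5.29 to 17.7). Adjacent probes were called together, so these intervals are too narrow, and others may also include it. The core word share (1.32%) was 2.67% with normexp, 3.24% with loess, 4.03% with 20 bins of input signal, 0% with stricter tails and 4.79% with GC and input bins, and 0.893% to 1.74% on each array alone. It passed all 59 permutations with loess and both of the input-binned settings, and not otherwise. The cause was not tested.

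The pluripotency list stayed above its random lists under all 11 alternatives. The 3 lists that stood apart became 5 with normexp, loess, 20 bins of input signal, and GC and input bins, where keratins and liver and plasma proteins lay below, and 4 on each array alone, with the GC trend removed or also matched on GC (trophectoderm below, percentile 1.22 with the trend removed alone) and with only probes well above background (liver and plasma proteins below, 1.62). Of the 41 named bound genes, 27 stayed with stricter tails and 36 with normexp. With loess, 20 bins of input signal, and GC and input bins, 37 or more stayed. The same held with the GC trend removed, the error model and a spread from the median absolute deviation. Named genes were not counted under the other alternatives, such as each array alone.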

Other observations

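The correction for GC content and input signal, the test of ribosomal protein shares with a region, the test of the core word within its own probes and the octamer test were chosen after the results they bear on had been seen, as were the comparisons of slopes over shared ranges of GC content and the requirement that a word pass its permutations by more than its 95% interval. The design held a single group, so no difference between conditions could be set against these explanations.

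With the GC and input trends removed together, 15 of the 42 pluripotency genes had a region, against 9 before, a mean of 1.05 in random lists (central 95%, 0 to 3) and 0 with the sign turned. The added members were Klf2, Mybl2, Dppa3, Il6st, Fbxo15 and Tfcp2l1. Nodal and its antagonist Lefty1 were then the 2 bound genes of the left-right list, and the Hedgehog receptor gene Ptch1 joined Zic2 and Zic5. Fgf5, Pax6 and Nkx2-2 of the neurectoderm list, Tfap2c and Fgfr2 of the trophectoderm list, and Rps10 and Rps19 of the ribosomal list were also bound. Their counts lay within those of random lists: 2 left-right genes against 0 to 2, 3 Hedgehog and Zic genes against 0 to 3, 3 neurectoderm genes against 0 to 4, 2 trophectoderm genes against 0 to 2, and 2 ribosomal genes against 0 to 4. With the sign turned, 4 ribosomal genes and 1 neurectoderm gene were called, and 0 of the other lists named here. The corrected scores were 2.22 for Fgf5, 2.00 for Pax6, 2.09 for Tfap2c and 2.23 for Zscan10, an ES cell zinc finger gene outside the lists. In all, 298 genes were bound against 149 with the sign turned, 129 of them shared with the main rule, and 122 genes were bound under the main rule, normexp, loess, input bins, GC removal and the joint correction alike.

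That pluripotency promoters ranked highest may come from occupancy in the Zic3 ChIP. GC content of these promoters alone did not account for it: with the GC trend removed and lists matched on GC too, the list still exceeded all random lists (percentile 100). Unspecific recovery of strongly transcribed promoters remains open for part of the shift in medians, since the ribosomal list also lay high, at a percentile of 99.87. Bound regions argue against it as their whole cause, provided that ribosomal genes are transcribed at least as strongly, which was not measured. Of 83 ribosomal genes, 0 had one (upper 95% limit 4.42%, and 8.37% for 2 of 83 after the joint correction), below the lower limits of 11.7% and 23.0% for the pluripotency list, though on array 1 alone the limits overlapped (8.97% and 4.54%). Random lists matched to the ribosomal one held a mean of 0.65 bound genes, so 0 by itself is no low count. No ChIP with another antibody was analysed here, so binding cannot be separated from open chromatin at these genes.

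The core word was the second pattern. After removal of the GC and input trends, 3572 probes with CAGCAGG had a mean log2 ratio of 0.15 ± 0.01 (SE over probes), above all of 59 letter permutations (percentile 100, highest permutation 0.08), which argues against base composition. A candidate explanation, hybridisation or labelling of the probe's own sequence, would not raise neighbours that lack the word. These 6725 neighbours had a mean of -0.06 ± 0.01, also above all permutations (percentile 100), but the highest permutation was at -0.06 too, and the lead was within the 95% interval of the mean, so a probe-sequence effect cannot be told apart from sequence preference of the precipitated protein. Neighbours at the next position no longer stood out (rank 13 of the word and its 59 permutations).

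The fall of the ratio with GC content was the third pattern. Lower recovery at promoter centres alone would flatten it elsewhere, but the slope more than 3000 bp upstream was 94.2% (92.3 to 96.3, gene bootstrap) of that within 1000 bp of the start. A composition bias of amplification, labelling or hybridisation could act on silent genes too. Olfactory and vomeronasal receptor genes were taken as silent in these cells, though their expression was not measured. Over all probes of olfactory receptor genes the slope was 4.72% of the general slope, but 95% of these probes lie below 44.9% GC. In that range the median over all probes first rises, from 0.07 at 20 to 25% GC to 0.35 at 30 to 35%, and falls only from there. The share depended on the range: over 35 to 50% GC it was 47.6% (41.9 to 52.0) for olfactory and 26.1% (12.6 to 39.5) for vomeronasal receptor genes, and over 40 to 50% GC 95.7% (84.3 to 106) and 79.8% (46.4 to 117), so a bias of this kind cannot be told apart from a difference between silent and active promoters.

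A further hypothesis was that Zic3 may share sites with octamer-binding factors such as Oct4. Probes next to those with ATTTGCAT had a mean corrected log2 ratio of 0.02, at a percentile of 66.6 among 734 permutations, so these neighbours gave no support for it. Probes with the word itself, where the probe's own sequence could act, had a mean of 0.00015. That lay at a percentile of 94.6 among the permutations.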
